A study of Mus musculus with 59 samples.

How the data were processed

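Primary mammary tumors of mice that carry the MMTV-PyMT transgene, from 3 groups, vehicle, methylparaben and propylparaben, were measured by RNA sequencing of total RNA from flash-frozen tissue, 59 libraries in all. Per the submitters' processing notes, reads were demultiplexed with bcl2fastq 2.20.0.422, aligned to GRCm38 with STAR 2.6.1d and counted with HTSeq 0.10.0. The annotation, the strand setting, the definition of introns and the tool used for normalization are not given in the sources used here. The authors deposited reads on 55421 genes with 5 HTSeq summary lines and, apart from these, intronic reads of 33282 genes, and the unit of the deposited values is a signal, described as normalized counts per the labels. Every value was a whole multiple of a factor per library (100 % of values within 1e-06 reads), so reads were recovered. The deposited values equal CPM scaled by trimmed mean of M values (TMM) factors, computed for each table separately, with a largest gap of 1.3e-13 % for genes and 3.3e-13 % for introns. GENCODE release M21 gave names and positions for 55154 gene identifiers, and 25976 genes were at 0 in every library. No column was left unused.

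Depth was the sum of recovered reads per library. Reads outside annotated features were 13.7 to 35.5 % (mean 18.5), reads aligned to several places 11.0 to 15.8 % (mean 12.8), ambiguous reads 0.65 to 0.84 % and mitochondrial reads 2.73 to 11.5 % of reads on genes. No duplicated libraries were seen: the lowest chi-square per degree of freedom between a pair of libraries of 1 group was 3.10, 2.72 and 2.12 over 9143 genes. Replicate numbers follow the order of the records, and no batch, date or animal is stated. No paired analysis was possible because the labels give no link between libraries of different groups.

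Values were analysed as log2(value + 1) with limma 3.58.1 (trend) in R 4.3.3 with the data.table package (version 1.17.8), in a single fit of all 59 libraries with 1 mean per group. Genes and introns with a mean of at least 1 were tested (14487 and 14281), and the difference between gene and intron level was tested where both means were at least 10 (6667). A call is an adjusted p under 0.05 (Benjamini-Hochberg within a comparison). Median SE of a gene's log2 fold change was 0.12 against vehicle. Gene lists were tested with camera at a preset correlation of 0.01 where at least 5 members were tested, which left out the salivary gland list with 4. The 40 lists covered targets of nuclear receptors and stress pathways, metabolism, the cell cycle, immune and epithelial states, and markers of the cell types and neighboring tissues that a tumor piece can hold. Single values per library were compared with two-sided permutation tests of 100000 resamples, adjusted within their family. Agreement between the esters was set against 100 relabellings of the libraries and 100 splits of the vehicle libraries into groups of 9 and 10. Named genes were chosen by a rule: up to 10 per direction with the largest fold change among those that passed, up to 4 members with the smallest p in the direction of each called list, and a few fixed genes whatever their values, among them Esr1, Pgr, Greb1, Mki67, Cyp1a1, Pparg and Cd8a. Where fewer than 3 genes passed, the rule took the 5 genes with the smallest p in each direction, named as not passing. The groups, comparisons, tests, lists, naming rule and the alternatives of the next paragraph, apart from those named as later, were set before the data were examined. Introns of genes named in the text, list medians with single libraries left out, values without methylparaben replicate 5, and the signs of genes picked by p in relabelled libraries were looked up after the gene results were seen.

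Alternatives were a pseudocount of 0.5 or 10, no filter, a mean of at least 100, TMM and median-of-ratios scaling of the deposited values, quantile normalization, only the 2 groups compared, array weights, robust empirical Bayes, 6 tissue composition scores (adipocyte, muscle, B cell, T cell, macrophage, fibroblast) as covariates, the tumor number as covariate, each of the 59 libraries left out, camera with an estimated correlation, fry, and count tests on recovered reads with edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0. The edgeR test called 559 genes for methylparaben against vehicle, 21 for propylparaben against vehicle and 21 between the esters. DESeq2 gave no adjusted p for 2247 genes of the propylparaben comparison. Chosen after seeing the data were a mean of at least 10, leaving out 5 libraries with a scaling factor under 0.9 (vehicle replicates 1 and 2 and methylparaben replicates 1, 5 and 16), leaving out the 7 libraries lowest on the first principal component, and the share of reads outside features, the mitosis score or the first principal component as covariate.

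The procedure was tested on simulated data drawn from negative binomial distributions with the means, dispersions and library sizes of the real data, with 100 genes changed 1.5-fold and 100 changed 2-fold, up or down. For genes limma recovered 53 and 83 % of them for methylparaben and 64 and 85 % for propylparaben, with 5.56 and 6.29 % of calls wrong. For introns it recovered 38 and 71 % and 43 and 58 %. Each gene was drawn independently, so variation shared by many genes was not simulated. In the real data the first principal component held 19.1 % of the variance. The share of wrong calls in the simulation therefore does not carry over to these tumors. Counts cover reads without molecular identifiers, so counting error is not the error of independent molecules. Raw reads, isoforms and DNA were not analysed here.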

Results

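RNA was sequenced from primary mammary tumors of mice carrying the polyoma middle T oncogene under the mouse mammary tumor virus promoter (MMTV-PyMT), a model in which tumors arise in the mammary epithelium. The labels place the 59 libraries in 3 groups: vehicle (n = 19), methylparaben (n = 20) and propylparaben (n = 20). Both compounds are preservatives, the methyl and the propyl ester of para-hydroxybenzoic acid. The series asks what long-term low-level exposure to parabens does to mammary tumors. Doses, exposure times and dates are not in the labels. The labels also do not state that each library comes from a separate animal, so the p-values measure the spread between these samples. Each library held between 1166500 and 2032790 reads on genes (mean 1595230 ± 207829, SD). The means were 1624080 in vehicle, 1577480 in methylparaben and 1585570 in propylparaben. Between 16268 and 18273 genes had at least 1 read in a library, and between 307255 and 1059350 reads per library fell in introns. In 18 permutation tests of depth, intronic reads, reads outside features, reads aligned to several places, mitochondrial share and scaling factor, the smallest adjusted p was 0.347. Propylparaben libraries differed from vehicle by -0.790 percentage points in reads aligned to several places (unadjusted p = 0.0386). Their mitochondrial share differed by -0.528 points (unadjusted p = 0.0297). Levels are given as scaled CPM (counts scaled to a common library size), mean ± SD, and fold changes as log2 ± SE.

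Methylparaben against vehicle asks which transcripts differed in tumors of animals given the methyl ester. With limma, 191 of 14487 tested genes passed: 99 rose and 92 fell, with absolute log2 fold changes from 0.19 to 1.36. Esr1, which encodes estrogen receptor alpha, rose from 11.5 ± 7.31 to 19.6 ± 7.75 (log2 0.88 ± 0.23, adjusted p = 0.0400) and was above the vehicle median in 19 of 20 tumors. Gata3, a transcription factor of luminal mammary cells, rose from 350 ± 150 to 472 ± 66.1 (log2 0.56 ± 0.14, adjusted p = 0.0355), with all 20 tumors above the vehicle median. The cyclin genes Ccna2 and Ccnb1, which drive entry into mitosis, fell by 0.49 ± 0.13 (adjusted p = 0.0456) and by 0.63 ± 0.17 (adjusted p = 0.0492) on the log2 scale. Without methylparaben replicate 5 Gata3 kept its call (adjusted p = 0.0395). Esr1 (log2 0.82, adjusted p = 0.0651), Ccna2 (0.0741) and Ccnb1 (0.0770) then did not pass. That library held Esr1 at 44.5, against a mean of 18.3 in the other 19 methylparaben tumors.

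Among the genes with large rises, Tppp, a tubulin-binding protein, rose from 5.39 ± 3.46 to 12.8 ± 7.17 (log2 1.22 ± 0.27, adjusted p = 0.0262, 20 of 20 tumors). Zfp385b (log2 1.07), the tetraspanin gene Tspan8 (1.05), the actin regulator Cap2 (1.03) and the potassium channel gene Kcnd2 (1.01) followed. The ubiquitin ligase gene Peli2 (1.01), Meltf (0.91), Apol6 (0.90) and the homeobox gene Msx1 (0.90) also rose. The adjusted p of these 8 genes lay between 0.0262 and 0.0460. Without methylparaben replicate 5 Zfp385b, Tspan8, Cap2, Meltf and Apol6 did not pass (adjusted p from 0.0531 to 0.0721). Tppp, Kcnd2, Peli2 and Msx1 kept their calls (0.0395 to 0.0459). That library held Cap2 at 25.9 and Apol6 at 58.4, against means of 3.73 and 16.1 in the other methylparaben tumors.

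Among the genes that fell, Rcor2, a corepressor, went from 16.1 ± 13.8 to 4.97 ± 3.06 (log2 -1.19 ± 0.31, adjusted p = 0.0401), with 19 of 20 tumors below the vehicle median. The histone gene Hist3h2ba fell by 1.01 ± 0.22 and the guanine nucleotide exchange factor gene Arhgef39 by 0.79 ± 0.17 (adjusted p = 0.0239 for both). Sgo1, which protects cohesin when chromosomes segregate, fell by 0.70 ± 0.17 (adjusted p = 0.0355). Faah, which degrades endocannabinoids (log2 -0.82), Kifc5b (-0.79) and Egln3, an oxygen-sensing prolyl hydroxylase (-0.76), fell as well. So did Dnph1, Parpbp and Pik3r3, each at log2 -0.71. Without methylparaben replicate 5 Hist3h2ba, Arhgef39 and Parpbp kept their calls (adjusted p from 0.0382 to 0.0391). Rcor2, Sgo1, Faah, Kifc5b, Egln3, Dnph1 and Pik3r3 then did not pass (0.0553 to 0.0741). Kifc5b is a near copy of Kifc1, so its reads cannot be assigned with certainty. The strand setting is not given, so reads of Apol6 may not be fully parted from those of Mb, which overlaps it on the other strand. Overlap was taken over whole genes, and whether exons overlap was not checked. Of 41 named genes checked, 21 overlap an annotated gene on the other strand, among them Tppp, Zfp385b, Tspan8, Cap2, Peli2, Kifc5b, Parpbp, Pparg, Mki67 and Greb1.

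On GRCm38, Esr1 (ENSMUSG00000019768) lies on chromosome 10 from 4611593 to 5005614. Tppp (ENSMUSG00000021573) lies on chromosome 13 from 74009407 to 74035753. Rcor2 lies on chromosome 19 from 7267325 to 7275225 and Arhgef39 on chromosome 4 from 43496142 to 43499695. Of the hormone and growth genes fixed in advance, Pgr, the progesterone receptor gene, differed by log2 1.01 ± 0.34 (adjusted p = 0.0865). Pparg, a regulator of fat cells, differed by 0.89 ± 0.26 (adjusted p = 0.0538) and Mki67, a marker of dividing cells, by -0.37 ± 0.14 (adjusted p = 0.103). None of these 3 passed. The estrogen target Greb1 (log2 0.06, adjusted p = 0.908) and Cd8a, a marker of cytotoxic T cells (0.05, adjusted p = 0.917), did not pass either. Cyp1a1 was not tested, at a mean level of 0.0733.

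Of the 39 fixed gene lists tested, 19 passed camera with its preset correlation in methylparaben tumors, 14 upward and 5 downward. Genes of mitosis fell as a group (median log2 -0.46, all 20 below 0, adjusted p = 2.09e-12), and so did those of DNA replication (median -0.33, all 20 below 0, adjusted p = 6.74e-10). Both lists had adjusted p = 0.433 with an estimated correlation. In the mitosis list Ccna2 and Ccnb1 fell and the other 18 did not pass, such as Cdc20 (log2 -0.62, adjusted p = 0.0541) and Ccnb2 (-0.50, adjusted p = 0.0666). All 20 passed when adjusted over the list alone. In the replication list the licensing factor gene Cdt1 fell (log2 -0.47 ± 0.12, adjusted p = 0.0400, or 0.0601 without methylparaben replicate 5). Rfc3 (-0.35), Pole (-0.61) and E2f1 (-0.44) did not pass. There 13 members passed when adjusted over the list alone. Estrogen receptor targets rose as a group (median log2 0.37, 15 of 17 above 0, adjusted p = 0.000120, and adjusted p = 0.433 with an estimated correlation). Esr1 alone passed among them, and 7 members passed when adjusted over the list alone. Cited1 (log2 1.03), Stc2 (0.89) and Nrip1 (0.28) did not pass. The mean target score was 5.09 ± 0.53 in vehicle and 5.49 ± 0.22 in methylparaben tumors (difference 0.40, 95 % interval 0.16 to 0.64). Vehicle replicates 7, 8, 10, 13, 14 and 19 and propylparaben replicate 1 were the 7 libraries lowest on the first principal component, with high mitosis and low target scores. The 6 vehicle libraries averaged 4.48 on the target score and the other 13 averaged 5.37. Without the 7 libraries the target score differed by 0.12 (interval -0.07 to 0.31, adjusted p of the list 0.0588). The mitosis score then differed by -0.18 (-0.46 to 0.09), against -0.46 with them, and the list kept its call (adjusted p = 6.39e-05). Immediate early genes rose (median 0.23, adjusted p = 0.00100, and adjusted p = 0.474 with an estimated correlation), and Jun was the one member that passed (log2 0.45 ± 0.10, adjusted p = 0.0301). Circadian clock genes rose (median 0.25, adjusted p = 0.00476, and adjusted p = 0.433 with an estimated correlation), with the core activator Arntl at log2 0.45 (adjusted p = 0.0510).

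Markers of cells other than tumor epithelium rose alongside those groups. Adipocyte markers had a median log2 change of 1.24 (13 of 13 above 0, adjusted p = 9.30e-07, 11 members adjusted over the list alone). Fibroblast markers had one of 0.58 (14 of 14 above 0, adjusted p = 8.68e-06, 10 members). With an estimated correlation both lists had adjusted p = 0.474. Without the 7 libraries lowest on the first principal component the fibroblast score differed by 0.145 (95 % interval -0.268 to 0.558), against 0.543 with them. The adipocyte score then differed by 0.644 (-0.296 to 1.58), against 1.11. The same adjusted p, 0.474 with an estimated correlation, held for the endothelial (median 0.23), basal (0.55), mesenchymal (0.36) and brown fat (0.66) lists, which rose with preset adjusted p from 0.000342 to 0.00476. Without the same 7 libraries the mesenchymal score differed by 0.0994 (-0.132 to 0.331), against 0.314, and the basal score by 0.287 (-0.121 to 0.695), against 0.441. The endothelial score changed little (0.273, interval 0.034 to 0.511, against 0.306), as did the brown fat score (0.62, -0.0863 to 1.33, against 0.699). Without methylparaben replicate 5 the brown fat median was 0.29 (score difference 0.38, against 0.70 with it), and the list was not tested, as 4 of its 6 members kept a mean of at least 1. The adipocyte median was 1.02 without that library. Examples were the lipid carrier gene Fabp4 (38.6 ± 26.8 to 232 ± 586, or to 103 ± 84.9 without replicate 5, which held 2697) and the proteoglycan gene Dcn (236 ± 139 to 376 ± 134, adjusted p = 0.0538). The collagen gene Col3a1 (log2 0.65), the vessel gene Robo4 (0.57) and the basal keratin gene Krt5 (0.85) did not pass genome-wide, nor did Fabp4 and Dcn. Skeletal muscle genes (median 1.20, or 0.90 without replicate 5, adjusted p = 0.00265) and antigen presentation genes (12 of 14 above 0, adjusted p = 0.00476) rose, with adjusted p = 0.518 and 0.493 with an estimated correlation. Skin keratin genes (median 0.45, adjusted p = 0.0174) rose, with adjusted p = 0.493 with an estimated correlation and a score difference of 0.45 (95 % interval -0.08 to 0.98). Methylparaben replicates 6, 7, 10 and 20 had skin scores from 3.24 to 5.12, and the median score was 1.08 in methylparaben and 0.993 in vehicle tumors. Genes of fatty acid oxidation (0.17, or 0.06 without replicate 5, adjusted p = 0.0197) and luminal markers (0.06, or 0.10 without replicate 5 and 0.09 without vehicle replicate 13, adjusted p = 0.0300) rose by small margins, with adjusted p = 0.529 and 0.493 with an estimated correlation.

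Downward, ribosomal protein genes (median -0.12, adjusted p = 0.000369), hypoxia genes (-0.22, adjusted p = 0.0119) and p53 targets (-0.14, adjusted p = 0.0221) fell. Each had adjusted p = 0.493 with an estimated correlation. Without the 7 libraries lowest on the first principal component these lists did not pass. The medians were then -0.05 for ribosomal protein genes (adjusted p = 0.065), 0.03 for hypoxia genes (0.87) and -0.07 for p53 targets (0.156). Egln3 was the hypoxia gene that passed, the carbonic anhydrase gene Car9 did not (log2 -0.69), and the cell death gene Bax of the p53 list was at -0.53 (adjusted p = 0.0510). By fry, which tests whether genes move on balance one way without comparing them with other genes, 6 lists passed. These were mitosis, replication, estrogen targets, endothelial, immediate early and circadian genes (adjusted p from 0.0181 to 0.0399).

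The count of 191 genes ranged from 1 to 932 when single libraries were left out (1 without vehicle replicate 8, 932 without vehicle replicate 5), and was 5 without the 5 libraries with low scaling factors, 0 without the 7 libraries lowest on the first principal component, 2 when the propylparaben libraries were left out of the fit and 0 with 6 tissue scores as covariates. Esr1, Gata3 and Ccnb1 kept their calls in 39, 49 and 20 of the 59 fits that left out a library (highest adjusted p 0.0855 and 0.0784 without vehicle replicate 10 and 0.101 without vehicle replicate 8). Lists lost theirs without methylparaben replicate 5 (fatty acid oxidation, adjusted p = 0.211), methylparaben replicate 10 (skin, 0.152) and vehicle replicate 4 (luminal, 0.184, and p53, 0.0511). Skin genes lost theirs in 3 of the 59 fits and luminal genes in 6. Nuclear respiratory chain genes, at a median of 0.01 with all libraries, gained a call downward without methylparaben replicate 5 (median -0.08, adjusted p = 0.00151). Glucocorticoid receptor targets gained one in 17 fits (adjusted p down to 0.0245), plasma cell genes in 4, macrophage genes in 3 and cholesterol synthesis genes in 2.

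**Figure D1:**
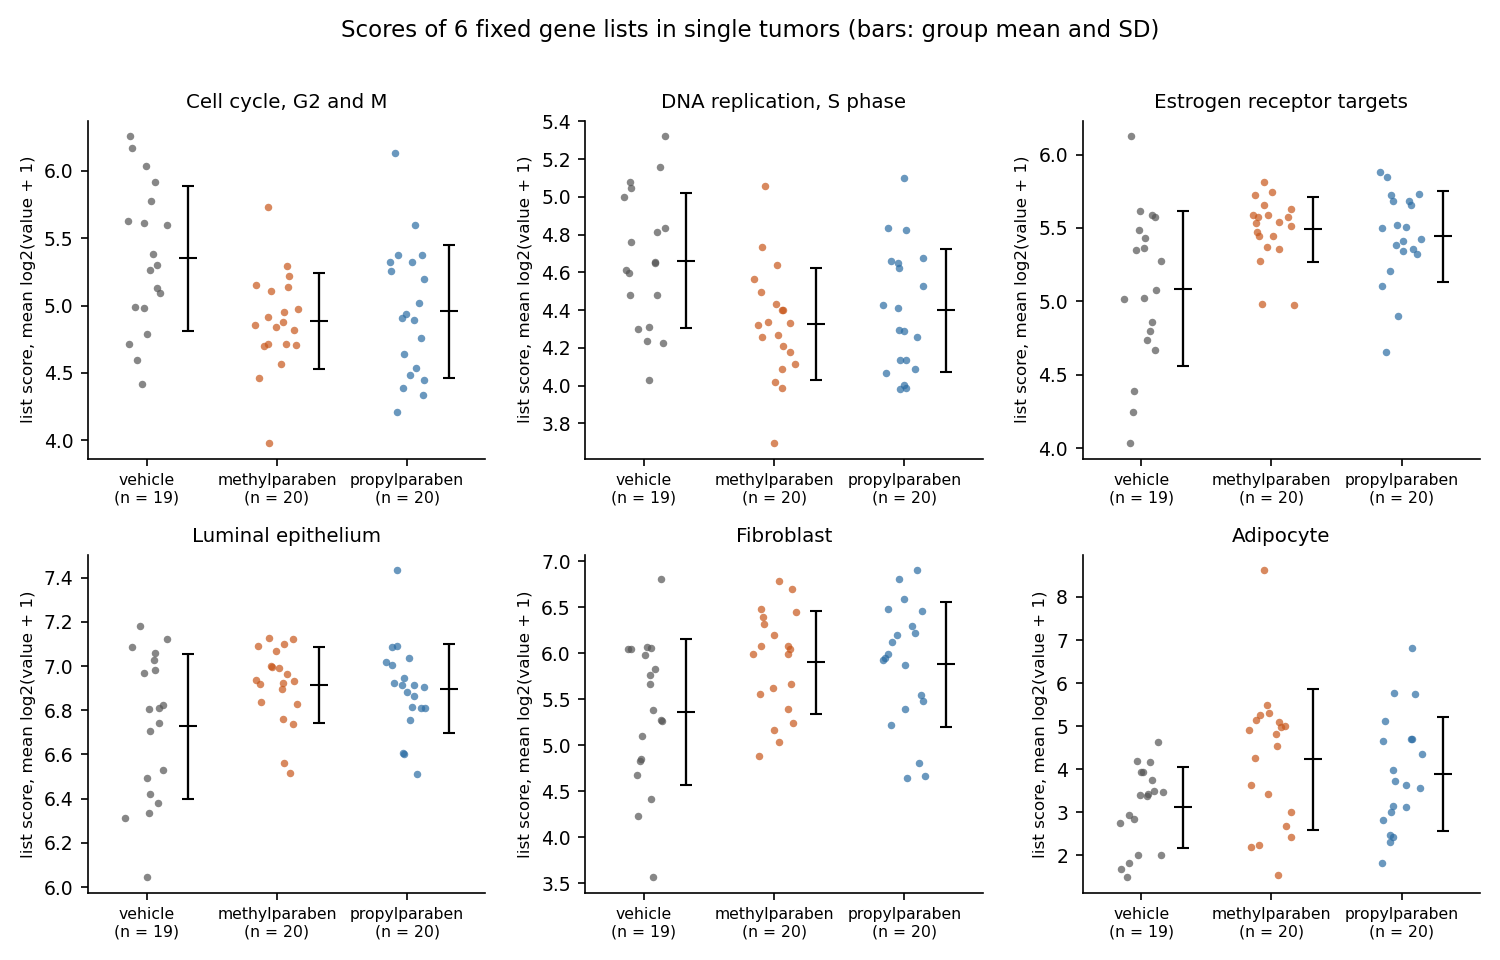
Each of the 6 panels plots the score of a gene list (vertical axis, mean log2(value + 1)) for every tumor in the vehicle (n = 19), methylparaben (n = 20) and propylparaben (n = 20) groups, with points for tumors and bars for the mean and SD. The estrogen target score averaged 5.09 in vehicle, 5.49 in methylparaben and 5.44 in propylparaben tumors.

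Propylparaben against vehicle asks the same of the propyl ester. By limma 4 genes rose and 0 fell. At an unadjusted p under 0.05 there were 1292 genes above and 1375 below vehicle, edgeR called 21 genes and DESeq2 227. Arhgef6, an exchange factor for Rac and Cdc42, rose from 106 ± 40.8 to 169 ± 40.5 (log2 0.75 ± 0.14, adjusted p = 0.0167, 18 of 20 tumors above the vehicle median). Irs1, the adaptor that couples insulin and IGF1 receptors to PI3 kinase, rose from 65.9 ± 27.5 to 99.4 ± 25.1 (log2 0.64 ± 0.13, adjusted p = 0.0252, 20 of 20). Pdgfd, a platelet-derived growth factor, rose from 2.45 ± 1.15 to 4.58 ± 1.41 (log2 0.73 ± 0.15, adjusted p = 0.0252, 17 of 20). Otud1, a deubiquitinase gene, rose from 9.15 ± 4.69 to 14.3 ± 3.49 (log2 0.68 ± 0.14, adjusted p = 0.0436, 20 of 20).

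On GRCm38, Arhgef6 lies on chromosome X from 57231485 to 57338729 and Irs1 on chromosome 1 from 82233101 to 82291416. Pdgfd lies on chromosome 9 from 6168584 to 6378850 and Otud1 on chromosome 2 from 19657752 to 19660583. Pdgfd and Irs1 overlap Ddi1 and Gm9747 on the other strand, so their reads may not be fully parted. Whether the exons overlap was not checked. Esr1 (log2 0.87, adjusted p = 0.0681, 17 of 20 tumors above the vehicle median) did not pass. Neither did Pgr (0.60, adjusted p = 0.345), Pparg (0.45, adjusted p = 0.342), Mki67 (-0.28, adjusted p = 0.263), Greb1 (-0.18, adjusted p = 0.706) and Cd8a (0.14, adjusted p = 0.750).

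Of the gene lists, 23 of 39 passed camera with its preset correlation, 15 upward and 8 downward, with 0 single members past the genome-wide threshold in any of them. Mitosis genes fell as a group (median log2 -0.40, all 20 below 0, adjusted p = 9.89e-10, 14 members adjusted over the list alone). Replication genes (median -0.28, all 20 below 0, adjusted p = 1.02e-06, 6 members) and ribosomal protein genes (median -0.17, 19 of 20 below 0, adjusted p = 1.82e-08, 13 members) fell too. Estrogen receptor targets rose (median 0.32, 15 of 17 above 0, adjusted p = 0.000212, 3 members), and fibroblast markers rose (13 of 14 above 0, adjusted p = 1.47e-06, 10 members). With an estimated correlation the adjusted p was 0.403 for all 5 of these lists. Examples that did not pass genome-wide were Ccnb1 (32.0 ± 13.2 to 22.2 ± 9.31, adjusted p = 0.116), Ccnb2 (log2 -0.52), Rfc3 (-0.34) and Rpl8 (-0.22). Cited1 (1.18, adjusted p = 0.0774), Stc2 (0.83), Pdgfra (0.58) and Col1a2 (0.61) also did not pass.

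Adipocyte markers rose by a median of 0.89 (13 of 13 above 0, adjusted p = 0.000363, 0 members adjusted over the list alone). Antigen presentation (12 of 14 above 0, adjusted p = 0.00292), basal (median 0.42, adjusted p = 0.00732) and luminal genes (0.13, adjusted p = 0.0222) also rose. These 4 lists had adjusted p = 0.427 with an estimated correlation. Endothelial (median 0.26, adjusted p = 0.00187), mesenchymal (0.34, adjusted p = 0.00567) and clock genes (0.20, adjusted p = 0.0117) rose, as did glucocorticoid receptor targets (0.30, adjusted p = 0.0162), unfolded protein response genes (0.10, adjusted p = 0.0222) and plasma cell genes (0.56, adjusted p = 0.0293). Each of them had adjusted p = 0.403 with an estimated correlation. Macrophage markers (median 0.19, 14 of 14 above 0, adjusted p = 0.0117), immediate early genes (0.12, adjusted p = 0.0273) and muscle genes (0.76, adjusted p = 0.0370) rose as well. With an estimated correlation they had adjusted p = 0.473, 0.427 and 0.623. Without the 7 libraries lowest on the first principal component these lists did not pass. The macrophage median was then -0.09 (adjusted p = 0.1), the immediate early median 0.04 (0.0806) and the muscle median 0.23 (0.318). Antigen presentation, luminal, mesenchymal, clock, unfolded protein response and plasma cell genes did not pass there either (adjusted p from 0.0518 to 0.203). Adipocyte, basal, endothelial and glucocorticoid receptor target lists kept their calls. Of their score differences there, only the endothelial interval left out 0 (0.241, interval 0.000398 to 0.482). The adipocyte score differed by 0.421 (-0.529 to 1.37) and the basal score by 0.221 (-0.191 to 0.632). The glucocorticoid receptor target score differed by 0.147 (-0.063 to 0.358). With all libraries the adipocyte (-0.0814 to 1.63) and basal intervals (-0.0738 to 0.694) held 0 as well. The vessel receptor gene Tek (log2 0.66), Gata3 (0.49, adjusted p = 0.0774), the glucocorticoid target Klf9 (0.39, adjusted p = 0.0662) and the chaperone gene Hsp90b1 (0.21) did not pass genome-wide. The immunoglobulin gene Ighm (0.77) and the macrophage gene Adgre1 (0.34) did not pass either.

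Hypoxia genes (median -0.22, adjusted p = 0.00242), p53 targets (14 of 15 below 0, adjusted p = 0.00242) and cholesterol synthesis genes (-0.15, adjusted p = 0.00332) fell. Each had adjusted p = 0.403 with an estimated correlation. Without the 7 libraries lowest on the first principal component hypoxia and cholesterol synthesis genes did not pass. Their medians were then -0.04 (adjusted p = 0.367) and -0.08 (0.0806). The p53 targets kept their call there (median -0.11, adjusted p = 0.0147), with a score difference of -0.123 (interval -0.264 to 0.0182). Vegfa, a vessel growth factor gene, was at 57.5 ± 41.2 in vehicle and 28.6 ± 16.7 in propylparaben tumors (log2 -0.81, adjusted p = 0.0897). Bax was at -0.52 and Mvd, an enzyme of cholesterol synthesis, at -0.44, both short of the threshold. Respiratory chain genes encoded in the nucleus (median -0.12, 19 of 20 below 0, adjusted p = 0.00242) and in the mitochondrion (-0.17, 7 of 7 below 0, adjusted p = 0.0347) fell by small margins. They had adjusted p = 0.473 and 0.474 with an estimated correlation. By fry, 0 of the lists passed (smallest adjusted p 0.0845, unadjusted p = 0.00352).

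The gene count ranged from 1 to 424 when single libraries were left out (1 without vehicle replicate 10, 424 without vehicle replicate 5) and was 0 with 6 tissue scores as covariates, without the 7 libraries lowest on the first principal component or when the methylparaben libraries were left out of the fit. Without those 7 the mitosis score differed by -0.17 (95 % interval -0.45 to 0.11), against -0.39 with them, and the estrogen target score by 0.12 (-0.08 to 0.31), against 0.35. Of these lists mitosis kept its call (adjusted p = 0.000581) and estrogen targets did not (adjusted p = 0.0764). Arhgef6 kept its call in all 59 fits that left out a library, Irs1 and Pdgfd in 48 (highest adjusted p 0.0715 without vehicle replicate 8 and 0.0720 without vehicle replicate 7) and Otud1 in 27 (0.104 without vehicle replicate 10). Lists lost their calls without vehicle replicates 1 (mitochondrial genes, adjusted p = 0.110), 4 (luminal, 0.138), 5 (muscle, 0.0959) and 8 (macrophage, 0.0885), and without propylparaben replicates 1 (unfolded protein response, 0.0684), 18 (immediate early, 0.0708) and 19 (plasma cell, 0.111). Muscle genes lost theirs in 21 of the 59 fits and mitochondrial genes in 11. The immediate early median was 0.07 without propylparaben replicate 18, 0.08 without vehicle replicate 4 and 0.18 without vehicle replicate 5, and the macrophage median 0.11 without vehicle replicate 8. Calls were gained by matrix enzymes in 6 fits, milk genes in 5 and oxidative stress genes in 4.

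**Figure D2:**
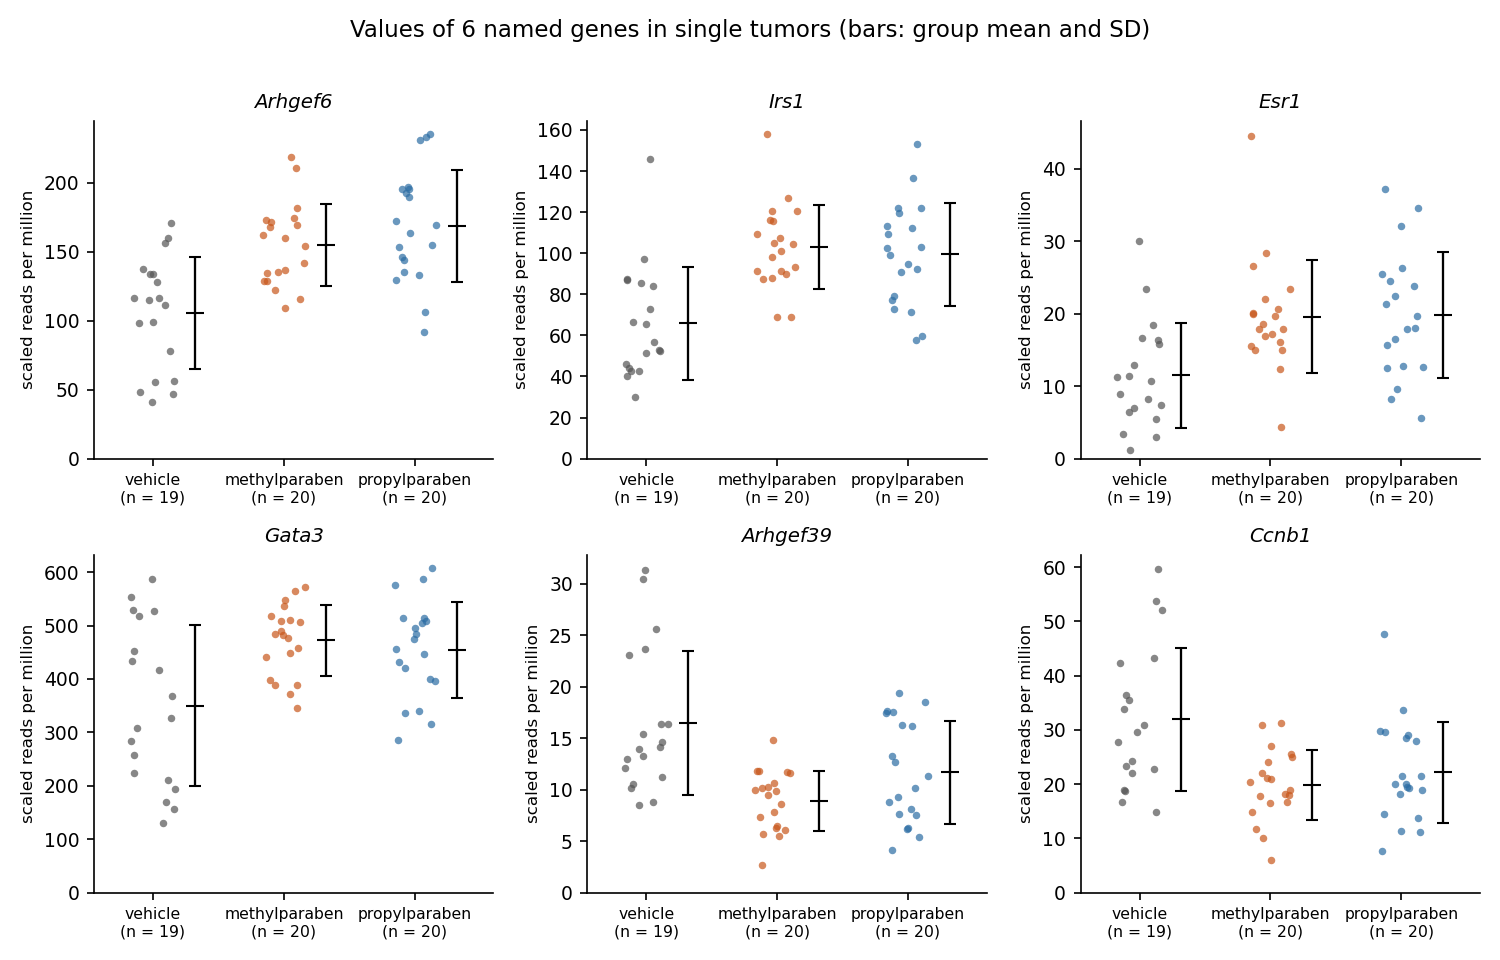
Levels of Arhgef6, Irs1, Esr1, Gata3, Arhgef39 and Ccnb1 (vertical axes, scaled CPM) in each tumor of the vehicle (n = 19), methylparaben (n = 20) and propylparaben (n = 20) groups, with points for tumors and bars for the mean and SD. Esr1 averaged 11.5, 19.6 and 19.9 in the 3 groups.

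Propylparaben against methylparaben compares tumors exposed to esters that differ in the length of the alkyl chain, at doses and times that the labels do not give. By limma 0 genes passed (311 at an unadjusted p under 0.05, smallest adjusted p 0.238). DESeq2 called 0 genes and edgeR 21, of which 1 was higher and 20 were lower with propylparaben. The 4 genes that rose with propylparaben also rose with methylparaben: Arhgef6 by log2 0.65 (adjusted p = 0.0239), Irs1 by 0.72 (adjusted p = 0.00806), Otud1 by 0.66 (adjusted p = 0.0239) and Pdgfd by 0.65 (adjusted p = 0.0276). The difference between the esters had 95 % intervals of -0.17 to 0.38 for Arhgef6, -0.33 to 0.18 for Irs1, -0.27 to 0.29 for Otud1 and -0.21 to 0.37 for Pdgfd. For Esr1 the difference was -0.02 (-0.47 to 0.43) and for Pgr -0.41 (-1.09 to 0.27). For Pparg it was -0.44 (-0.95 to 0.06), or -0.24 (-0.65 to 0.17) without methylparaben replicate 5, for Greb1 -0.24 (-0.69 to 0.21), for Mki67 0.09 (-0.18 to 0.36) and for Cd8a 0.09 (-0.32 to 0.50), or 0.04 without that library, where Esr1 was at 0.05. Cnst, which encodes a connexin trafficking protein, had the smallest p, at 9.58 ± 3.42 with methylparaben and 6.29 ± 1.80 with propylparaben. Its difference was log2 -0.53 ± 0.11 (interval -0.75 to -0.30), with 19 of 20 tumors below the methylparaben median. Rad9b (log2 -0.60), Iqcb1 (-0.35), Alkbh3 (-0.33) and Smcr8 (-0.23) on the lower side did not pass. On the higher side Cd247 (0.57), Ttc12 (0.56), Syt12 (0.52), Tnfrsf21 (0.29) and Cebpz (0.16) did not pass.

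Of 39 lists, 8 passed camera with its preset correlation, 1 upward and 7 downward with propylparaben relative to methylparaben. Random splits of the same libraries called a median of 11 lists, and 82 of 100 splits, the real one included, called at least 8. So the number of lists called is no sign of a difference between the esters. Skin keratin genes were lower (median log2 -0.69, 10 of 10 below 0, adjusted p = 2.22e-12, and adjusted p = 0.0811 with an estimated correlation), with 6 members passing when adjusted over the list alone. The skin barrier genes Flg (7.21 ± 18.9 with methylparaben, 0.110 with propylparaben) and Krt1 (7.04 ± 23.9 and 0.104 ± 0.221) varied widely between methylparaben tumors. Nuclear (median -0.10, adjusted p = 2.18e-06) and mitochondrial (-0.21, adjusted p = 0.000102) respiratory chain genes, brown fat genes (-0.48, adjusted p = 0.000376) and ribosomal protein genes (-0.04, adjusted p = 0.00548) were lower. Adipocyte (-0.33, adjusted p = 0.0119) and immediate early genes (-0.13, adjusted p = 0.0347) were lower as well, and replication genes were higher (0.08, adjusted p = 0.0131). Each of these 7 lists had adjusted p = 0.875 with an estimated correlation, and fry called 0 lists (smallest adjusted p 0.299, unadjusted p = 0.00767). Without methylparaben replicate 5 only 2 lists passed. The medians were then -0.08 for adipocyte (adjusted p = 0.717), -0.02 for nuclear (0.451) and -0.08 for mitochondrial respiratory chain (0.0770) and 0.04 for replication genes (0.258), and brown fat genes (-0.19) were not tested. Adipocyte and replication genes lost their calls in 7 and 9 of the 59 fits, with medians of -0.18 and 0.03 without propylparaben replicate 1. Immediate early genes lost their call in 14 of the 59 fits (median -0.08, adjusted p = 0.288 without propylparaben replicate 12), and ribosomal protein genes without methylparaben replicate 16 (median -0.03, adjusted p = 0.0577). Mitosis and muscle genes gained calls in 17 fits each, cholesterol synthesis genes in 8, fatty acid oxidation in 7, fatty acid synthesis in 6, and matrix enzymes and the unfolded protein response in 2 each.

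Across the 14487 genes the fold changes of the esters against the shared vehicle libraries had r = 0.856 (genes are not independent replicates) and covariance 0.0472. All 99 genes that rose with methylparaben were above 0 with propylparaben, 96 of them at an unadjusted p under 0.05. All 92 that fell were below 0, 85 of them at that level. They were picked against the same vehicle libraries, which makes signs agree by itself. As many genes picked by p in relabelled libraries agreed for means of 92.8 upward and 85.3 downward, and all of them did in 7 and 4 of 100 relabellings. With the real groups and different vehicle libraries for each ester the means were 90.8 and 84.7. No value without an effect was computed for that setting, and the relabelled values, which share controls, are no reference for it. Over all genes 82.8 % had the same sign, against a mean of 67.2 % in relabelled libraries (highest 78.3 %). Median changes with methylparaben and propylparaben were 0.55 and 0.42 for the genes that rose and -0.41 and -0.33 for those that fell. The esters differed by at most 0.49 and 0.40 in absolute terms, with median half-widths of the 95 % interval of 0.28 and 0.21. Sharing controls makes fold changes alike by itself. Relabelled libraries gave a mean r of 0.513 (highest of 100, 0.763) and a mean covariance of 0.0126 (highest 0.0346). With different vehicle libraries for each ester r averaged 0.502 (0.137 to 0.625) and covariance 0.0327. The relabelled r and covariance, which come from shared controls, are no reference for these values either, and none without an effect was computed. All 4 genes called with propylparaben were among the 99 called with methylparaben. Independent lists would share 0.0273, but these lists share their vehicle libraries, so that number does not measure agreement. A moderated F-test over all 3 groups called 73 genes, of which 64 were also called with methylparaben. Irs1, Arhgef6, Otud1 and Pdgfd were among the 73.

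**Figure D3:**
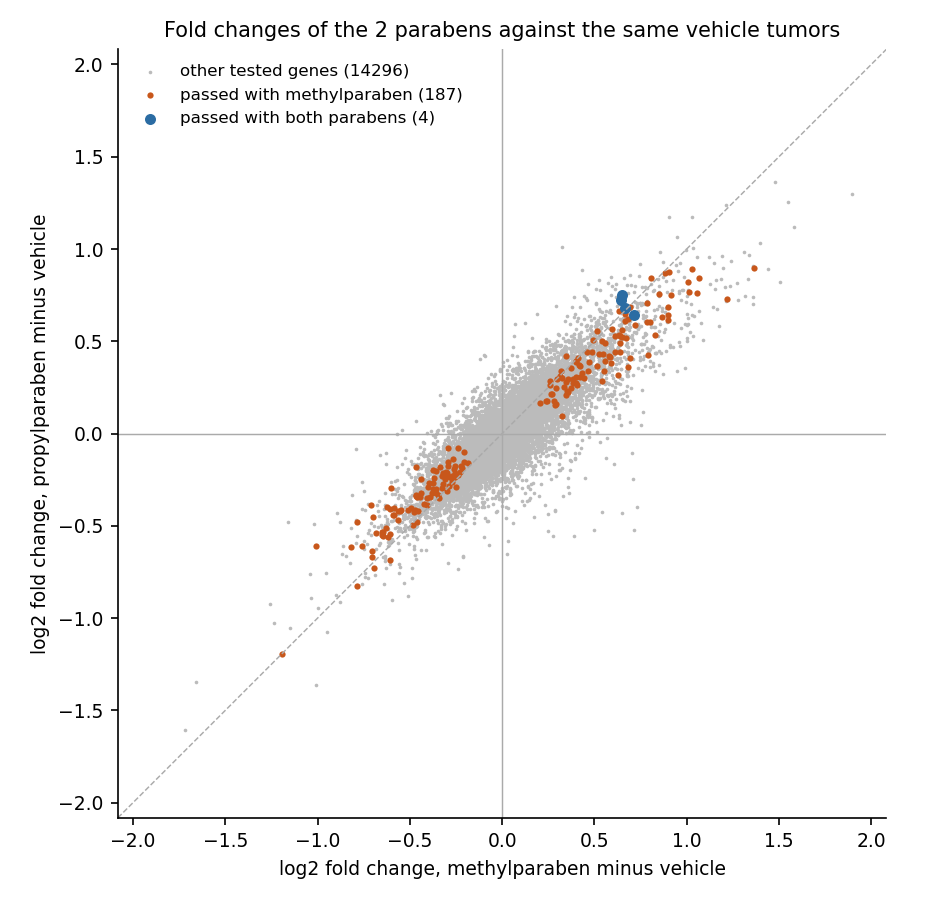
Each point is 1 of 14487 tested genes, with its log2 fold change of methylparaben against vehicle on the horizontal axis and of propylparaben against vehicle on the vertical axis, colored by whether it passed with methylparaben alone (187), with both esters (4) or with neither (14296). Pearson's r across genes was 0.856.

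Intronic reads, which follow unspliced transcripts, gave 0 genes past the threshold by limma among 14281 in each comparison. At an unadjusted p under 0.05 there were 1895 with methylparaben, 1725 with propylparaben and 496 between the esters, and edgeR called 48, 0 and 1. Introns of Peli2 (log2 0.98), Gata3 (0.53), Esr1 (0.53), Egln3 (-0.79) and Faah (-0.89) with methylparaben had the sign of the change in the gene table. So did introns of Arhgef6 (0.73) and Irs1 (0.60) with propylparaben. These are examples, and introns of the other named genes are not listed here. They come from the same libraries in which the gene changes were seen, so like signs are no separate support. The difference between gene and intron level, which would move if transcripts were spliced or degraded at another rate, passed for 0 of 6667 genes by limma in each comparison, with 418, 485 and 235 at an unadjusted p under 0.05.

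Tumors of the exposed groups lay closer to their own group's mean than vehicle tumors did. The median distance over all tested genes was 59.1 (SD 8.13) in vehicle and 49.9 (SD 14.2) in methylparaben (difference -9.13, adjusted p = 0.0235, two-sided permutation test). In propylparaben it was 51.1 (SD 8.73), a difference of -7.93 (adjusted p = 0.0200). With the mean in place of the median distance the methylparaben difference was -4.33 and did not pass (p = 0.261). Without the 7 libraries lowest on the first principal component, most of them vehicle, both median differences were smaller and neither passed. So the wider spread of the vehicle group rests in part on those libraries. They were picked as the low end of that component, so leaving them out narrows the vehicle group by construction. Why the vehicle group was wider is not shown by it.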

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

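The tests added after seeing the data were a mean of at least 10, leaving out the 5 libraries with low scaling factors, leaving out the 7 libraries lowest on the first principal component (vehicle replicates 7, 8, 10, 13, 14 and 19 and propylparaben replicate 1), and the share of reads outside features, the mitosis score or the first principal component as covariate. Of the 30 named gene results and 50 list results that passed, 29 and 49 still did with a pseudocount of 0.5, 29 and 50 with robust empirical Bayes, and all with TMM, quantile normalization or the tumor number as covariate. Fewer genes did with array weights (10), no filter (5), without the libraries with low scaling factors (3), with only the 2 groups compared (1), with composition scores (0) and without the 7 lowest libraries (0, with 28 lists). Of the lists 24 still passed with composition scores, 6 with fry and 0 with an estimated correlation. The counts of genes called moved as well. The cause was not tested for any of these moves, except where the construction shows it: a higher or lower minimum changes how many genes are tested, and leaving out libraries or a group changes how many samples are. Rescaling moved the median fold change of all genes by no more than from -0.01 to 0.01 with TMM or median-of-ratios factors, and to -0.02 with quantile normalization.

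For methylparaben against vehicle, 191 genes became 559 with edgeR, 640 with DESeq2, 334 at a mean of at least 10, 297 with the share of reads outside features as covariate, 80 at a mean of at least 100, 39 with array weights, 25 with no filter, 5 without the libraries with low scaling factors and 2 with only the 2 groups compared. The count was 0 with 6 composition scores, with the mitosis score and with the first principal component as covariate, and without the 7 lowest libraries. Of the calls, 51.8 % were upward, against 40.4 % of 240 with quantile normalization. For propylparaben against vehicle, 4 genes became 227 with DESeq2, 75 at a mean of at least 100, 21 with edgeR, 16 at a mean of at least 10, 9 with the share of reads outside features, 8 with the tumor number, 7 with TMM (85.7 % upward), 2 with no filter, and 0 with only the 2 groups compared, 6 composition scores, the mitosis score, the first principal component or without the 7 lowest libraries. Between the esters, 0 genes became 21 with edgeR and 1 with composition scores. The F-test count of 73 became 338 with edgeR, 7 with no filter, 5 without the libraries with low scaling factors, 3 with array weights and 0 with composition scores, the mitosis score, the first principal component or without the 7 lowest libraries.

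In introns, 0 calls for methylparaben became 48 with edgeR, 12 with the share of reads outside features, 8 with median-of-ratios factors, 7 at a mean of at least 10, 6 with a pseudocount of 10, and 2 at a mean of at least 100 or with array weights. For propylparaben they became 20 with the share of reads outside features and 6 with array weights, and between the esters 1 with edgeR. The difference between gene and intron level between the esters went from 0 calls to 2 with array weights and 1 with composition scores.

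Gene lists called, 19, 23 and 8 in the order methylparaben against vehicle, propylparaben against vehicle and propylparaben against methylparaben, became 0, 0 and 0 with an estimated correlation, 6, 0 and 0 with fry, 9, 14 and 4 with composition scores, 2, 3 and 4 at a mean of at least 100, and 16, 11 and 5 without the 7 lowest libraries. Between the esters there were 5 at a mean of at least 10 and 4 without the libraries with low scaling factors. With composition scores, which hold the adipocyte and muscle lists themselves, the direction of the camera test turned for 5 list results, none of which passed there: adipocyte markers (median -0.0227 for methylparaben against vehicle and -0.0194 between the esters), mesenchymal genes (-0.0643 for propylparaben), and, for methylparaben, fatty acid oxidation (0.0176) and muscle genes (0.000678). Without the 7 lowest libraries it turned for hypoxia genes with methylparaben (0.0327) and macrophage markers with methylparaben (-0.142, adjusted p = 0.00152) and propylparaben (-0.0907). The correlation of fold changes, 0.856 (jackknife SE 0.0688), was 0.935 at a mean of at least 100, 0.720 without the 7 lowest libraries, 0.687 with composition scores, 0.666 with the mitosis score, 0.625 with the first principal component and 0.502 with the vehicle libraries split between the esters. The last of these comes without shared vehicle libraries, so it is not on the scale of the others. The spread difference of methylparaben was -4.33 with the mean distance, and without the 7 lowest libraries -4.19 (p = 0.309) and -3.62 for propylparaben (p = 0.0702).

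Leaving out single libraries gave 1 to 932 genes for methylparaben against vehicle, 1 to 424 for propylparaben against vehicle, 0 to 1 between the esters (1 without propylparaben replicate 17) and 2 to 610 with the F-test. Introns gave 0 to 23, 0 to 10 and 0 to 0, the difference between gene and intron level 0 to 0, 0 to 0 and 0 to 1, lists 17 to 22, 19 to 25 and 2 to 11, and the correlation ran from 0.831 to 0.875. Methylparaben counts moved by over 1.5 times without vehicle replicates 1 (34), 2 (63), 3 (416), 5 (932), 6 (390), 7 (18), 8 (1), 9 (492), 10 (2), 11 (707), 12 (476), 14 (3), 15 (443), 17 (529), 18 (93) and 19 (23), methylparaben replicates 1 (403), 2 (73), 3 (70), 4 (423), 5 (53), 6 (27), 7 (61), 8 (38), 10 (88), 11 (59), 13 (67), 15 (63), 17 (78), 18 (95), 19 (359) and 20 (519), and propylparaben replicate 1 (310). Propylparaben counts did so without vehicle replicates 3 (88), 5 (424), 6 (94), 9 (86), 11 (128), 12 (91), 15 (114) and 17 (175), vehicle replicates 4, 7, 8, 10, 13, 14 and 19 (1 each), methylparaben replicate 5 (9), and propylparaben replicates 1 (319), 2 (7), 4 (65), 5 (2), 8 (1), 9 (9), 12 (96), 14 (1), 15 (20), 17 (1), 19 (2) and 20 (16). The F-test count moved in 50 of the 59 fits, to 119 without methylparaben replicate 1, 144 without methylparaben replicate 20, 298, 129 and 115 without propylparaben replicates 1, 4 and 12, 180, 189, 161, 334, 181, 259 and 276 without vehicle replicates 3, 6, 9, 11, 12, 15 and 17, and to 44 without propylparaben replicate 16. It was 610 without vehicle replicate 5, 2 without vehicle replicates 7, 8 or 10, 3 without vehicle replicate 14 and between 5 and 9 in the remaining fits that moved. Introns of the methylparaben comparison moved without 15 libraries (4 to 23 calls, 23 without vehicle replicate 5), those of propylparaben without propylparaben replicate 1 (10) and vehicle replicate 5 (6). Lists between the esters moved without methylparaben replicate 5 (2) and propylparaben replicates 1 (5) and 20 (5), and 1 gene of the difference between gene and intron level passed between the esters without methylparaben replicates 5, 13 or 18, propylparaben replicates 3 or 12 or vehicle replicate 17. At this depth simulated 1.5-fold changes were recovered for 53 % of genes with methylparaben and 64 % with propylparaben, and 38 and 43 % in introns, so smaller changes were often not detectable.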

Other observations

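The tests chosen after the result was seen were the comparison of luminal with mitosis scores, the count of fat and muscle markers in methylparaben replicate 5, the threshold for chromosome shifts, and the random splits of the libraries for the gene counts of both parabens against vehicle and for the correlation of their fold changes, the earlier draw of splits, the scores compared between its sides, the mitosis score set beside the luminal score of methylparaben replicate 5, the lists without that library, the scores without the 7 libraries lowest on the first principal component, the relations with fibroblast scores, and the intron shifts set against the chromosomes that were not shifted.

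Several lists of immune and detoxification genes passed in neither paraben group against vehicle. T cell markers had medians of 0.03 with methylparaben and 0.05 with propylparaben (adjusted p = 0.962 and 0.821), interferon response genes 0.04 and -0.05 (adjusted p = 0.962 and 0.727), and neutrophil markers -0.05 and -0.02 (adjusted p = 0.781 and 0.821). Markers of B cells (0.13 and 0.25), dendritic cells (0.15 and 0.21) and cytotoxic cells (0.11 and 0.23) had adjusted p from 0.105 to 0.432. Inflammatory cytokine genes had a median of 0.03 but a mean of -0.09 with methylparaben (adjusted p = 0.942), and 0.14 and -0.02 with propylparaben (adjusted p = 0.686). Targets of the aryl hydrocarbon receptor, which senses many foreign compounds, had a median of 0.03 and a mean of -0.15 with methylparaben (adjusted p = 0.451) and a median of -0.03 with propylparaben (adjusted p = 0.830). Genes of the oxidative stress response (0.11 and 0.11, adjusted p = 0.101 and 0.0678), milk genes (0.22 and 0.14, adjusted p = 0.256 and 0.0721) and matrix enzymes (0.08 and 0.17, adjusted p = 0.508 and 0.0721) did not pass. Fatty acid synthesis genes had a median of -0.03 and a mean of 0.04 with methylparaben (adjusted p = 0.745), and a median of -0.07 with propylparaben (adjusted p = 0.511). Lists called with propylparaben alone had, with methylparaben, adjusted p of 0.0544 (glucocorticoid receptor targets, median 0.27), 0.0814 (plasma cells, 0.46), 0.101 (macrophages, 0.19) and 0.101 (cholesterol synthesis, -0.07), and 0.262, 0.798 and 0.891 for the unfolded protein response, nuclear and mitochondrial respiratory chain genes. Without methylparaben replicate 5 the last 2 of these had medians of -0.08 and -0.07 (adjusted p = 0.00151 and 0.139), so for nuclear respiratory chain genes the call with propylparaben alone rests on that library. Glucocorticoid receptor targets passed with methylparaben in 17 of the 59 fits that left out a library, plasma cell genes in 4, macrophage genes in 3 and cholesterol synthesis genes in 2, so for these lists a call with propylparaben alone is not firm. Lists called with methylparaben alone had, with propylparaben, adjusted p of 0.17 (skin, -0.29, and fatty acid oxidation, 0.04) and 0.377 (brown fat, 0.09), and erythroid genes had 0.418 and 0.821.

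Within the vehicle group, tumors with higher estrogen receptor target scores had lower mitosis scores (r = -0.844, rho = -0.830, adjusted p = 6e-05, permutation test with 1e-05 the smallest p it can give, n = 19), and r was -0.771 without the 2 tumors with the farthest scores. In propylparaben tumors r was -0.657 (rho = -0.606, adjusted p = 0.00441, r = -0.567 without the 2 farthest), and in methylparaben tumors -0.218 (rho = -0.244, adjusted p = 0.455, n = 20). The luminal score had r = -0.606 in vehicle (rho = -0.647, adjusted p = 0.0133, r = -0.674 without the 2 farthest). It had r = 0.175 in methylparaben (rho = -0.195, adjusted p = 0.455, r = -0.309 without the 2 farthest) and -0.195 in propylparaben (rho = -0.340, adjusted p = 0.455, r = -0.383 without the 2 farthest). These 6 relations were computed first. In vehicle the fibroblast score followed the same axis, with r = -0.750 to the mitosis score and 0.793 to the target score. The relation of target and mitosis scores in vehicle was -0.617 given the fibroblast score, and -0.661 (n = 13) without the 6 vehicle libraries lowest on the first principal component. In propylparaben it was -0.483 given the fibroblast score. In methylparaben the sign of the luminal relation rests on those tumors, and whether the relations differ between groups was not tested.

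Mitosis genes were lower in both paraben groups while markers of fat and stroma were higher, so a lower share of epithelial tumor cells could account for the fall. Luminal scores did not fall with them. The luminal change exceeded the mitosis change by 0.651 (95 % interval 0.270 to 1.03) with methylparaben and by 0.562 (0.180 to 0.943) with propylparaben. This would argue against a lower share of luminal epithelium only if luminal scores followed the share of cells alone. In vehicle tumors luminal scores were lower where mitosis scores were higher (r = -0.606), so they cannot settle this. Normal gland holds luminal cells too, so these scores cannot tell whether normal gland had replaced part of the tumor cells. Without the libraries with low scaling factors the mitosis score differed by -0.407 (-0.729 to -0.0846) and -0.398 (-0.708 to -0.0881), and with the share of reads outside annotated features as covariate by -0.475 (-0.768 to -0.182) and -0.398 (-0.691 to -0.105), so neither removes the difference. Without the 7 libraries lowest on the first principal component, 6 of them vehicle, the mitosis score differed by -0.181 (-0.457 to 0.0941) and -0.172 (-0.451 to 0.106), so much of the fall rests on those vehicle tumors, although picking tumors with high mitosis scores (5.61 to 6.26) lowers it in part by construction. Exposure, a lower share of tumor cells with or without more normal gland, or tumors that differed in stage or size for another reason stay open. The labels give neither stage nor size.

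Methylparaben replicate 5 held fat, brown fat and muscle transcripts at the highest level of all libraries for 30 of 31 markers, the exception being Lep, which may come from other tissue in the piece that was sequenced. Ucp1 was at 745.6 against a mean of 0.909 in the other 58 libraries, Fabp4 at 2697 against 80.5, Acta1 at 1827 against 70.7 and Myh4 at 2453 against 65.5, and 11.5 % of its reads on genes were mitochondrial against at most 7.31 % elsewhere. A sample with no tumor stays open: its luminal score of 6.51 was inside the range of 6.04 to 7.43 over all libraries, but normal gland holds luminal cells too and no tumor-free tissue was sequenced, so that range was the wrong bound. Its mitosis score of 3.98 was the lowest of the 59.

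In 7 tumors (4 vehicle, 2 methylparaben, 1 propylparaben) the median gene of a whole chromosome was shifted by at least 0.15 on the log2 scale, 10 shifts among 1180 pairs of tumor and chromosome, all upward, and 4 of them on chromosome 11. They were chromosome 16 (0.34) and 18 (0.31) in vehicle replicate 4, chromosomes 7 (0.34), 11 (0.31) and 17 (0.17) in propylparaben replicate 15, and chromosome 11 in methylparaben replicates 4 (0.28) and 10 (0.20) and vehicle replicate 5 (0.18), with chromosome 17 in vehicle replicate 12 (0.18) and 7 in vehicle replicate 1 (0.16). The intron reads were shifted the same way beyond all other chromosomes of the tumor in 7 of 10, short of the 9 that were set to argue against scatter of the reads, as the other 3 lay under another shifted chromosome of their tumor. Beyond the chromosomes that were not shifted they lay in 10 of 10, which argues against scatter, and a few genes or one region are argued against as well, since at least 9 of 10 segments of the chromosome moved in that direction in 10 of 10. A gain of chromosome copies in these tumors is a candidate explanation and was not tested, as no DNA was analysed here.

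The libraries of each comparison were regrouped at random into 99 other splits. For the gene counts 1 of 100 splits, the real one, was as large for methylparaben (191 genes, 7 in the next) and for propylparaben (1 of 100, 4 against 1). In this draw no other split was as large for the F-test (1 of 100, 73 against 9) or for the correlation of fold changes (1 of 100, 0.856 against 0.785). For lists 4 of 100 splits were as large with methylparaben (19 against 21 in the largest other) and 1 of 100 with propylparaben (23 against 21). The random splits called a median of 11 and 9 lists. Between the esters 82 of 100 were as large (8 against 19), so that count is within what random splits give. These numbers of splits were not corrected for how many results were tested. For genes between the esters, introns and the difference between gene and intron level the real count was 0, so 100 of 100 splits were bound to be as large and nothing follows about chance (highest others 58 for genes, 1, 73 and 1 for introns, 6, 2 and 1 for the difference). An earlier draw of 30 splits held a random split with 530 genes for methylparaben and another with 154 for propylparaben, while the other 29 gave 0 in each. With the real one that made 2 of 31 splits as large for each paraben, and 2 of 130 over both draws. So splits as large were rare over both draws. Yet a random split gave a larger count than the real one for each paraben, so chance is not firmly excluded for these gene counts. In the splits with 530 and 154 genes the sides lay 0.884 and 0.951 SD apart on the first principal component, the farthest of 30 in each case, against medians of 0.243 and 0.166. They were also the farthest apart in the fibroblast score (1.02 and 0.876 SD) and second in the mitosis score (0.618 and 0.753 SD). The real groups lay 0.984 and 0.804 SD apart on the component, 0.745 and 0.671 in the fibroblast and 0.915 and 0.718 in the mitosis score. Splits that call this many genes point to a structure of the samples, and these scores, which were not told apart, may be part of it. With the first principal component or the mitosis score as covariate 0 genes were called for either paraben. Both covariates were computed from the same values, and the real groups lay apart on them. An exposure that moved these scores would lose its calls in the same way, so this cannot decide between exposure and another structure of the samples.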
